A study of Mus musculus with 6 samples.

How the data were processed

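RNA was measured in stomach corpus tissue of 6 C57BL/6 mice aged 6 months, 3 wild type (WT) and 3 carrying the R122C substitution in the transcription factor RUNX3. Each library came from 1 mouse, per the labels, so the replicates are animals. Per the labels' protocols, total RNA was purified on silica columns with DNase treatment, and a sequencing company prepared and sequenced the libraries. Zygosity, sex and strandedness are not given in the sources used here. STAR, featureCounts and the mouse build mm10 are named in the submitters' processing notes, without versions or settings.

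The deposited table holds 18708 rows of FPKM values (fragments scaled by transcript length and by library total), computed by the authors, with 2 decimals. How the authors turned counts into FPKM is not given in the sources used here. No row is at 0 in all 6 libraries. A spreadsheet date stands in place of the gene name in 26 rows, with 2 dates occurring more than once, and these rows were tested but are not named. FPKM sums differed between libraries, from 581276 in R122C 3 to 716992 in WT 3, so the values are not on a common total. Among genes with a mean of at least 1 FPKM, 8 share all their values with another row, among them the secretoglobins Scgb2b15 and Scgb2b17, and values of such near-identical genes are uncertain because the counting could split or duplicate their reads.

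Raw counts were not used here. In FPKM, 1 fragment has a fixed worth once gene length is known, so the spacing of low values was searched for a common step in genes with 1 annotated transcript in GENCODE M21 (build GRCm38, the same assembly as mm10). A step was accepted when the estimates with length limits of 1000 and 1500 nucleotides differed by at most 5% and the signal exceeded that of 100 permutations of the lengths. This gave about 42900000 fragments for WT 1, 38900000 for WT 2, 31700000 for WT 3 and 32200000 for R122C 3. No stable step was found for R122C 1 and R122C 2, whose depth is undetermined. These are estimates that rest on the annotation used, and no counting interval was derived from them.

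Values were tested as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 libraries entered the test, which left 11422. The pseudocount of 1 FPKM shrinks the change of low genes, so each log2 fold change is on the log2(FPKM + 1) scale. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The model had no covariate or block. For Runx3, which lies under the filter, an exact two-sided permutation test of the 6 values was used. With 3 against 3 the smallest p of that test is 0.1.

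Before the data were examined, 39 gene lists were fixed, covering cell types of the corpus and neighbouring tissue, proliferation, metaplasia, immunity, signalling and technical checks. The 36 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. The named genes followed a rule fixed at the same time. It takes Runx3, the 10 genes with the largest log2 fold change in each direction among those past the threshold with non-overlapping groups, up to 4 members past the threshold of each list or else its member of smallest p, and the first 2 members of each cell type list. Unnamed gene models and immunoglobulin or T cell receptor segments were left out of the largest changes. Other genes are said to be chosen after their values were seen. Gene positions are from GENCODE M21.

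On simulated data with 11422 genes made from these libraries, the test recovered 34% of 50 genes changed by 1 on the log2 scale and 100% of 50 genes at each of 2, 3 and 4, with 14 false calls among unchanged genes. The changed genes were drawn from those with a mean log2 value above 2. In 50 draws without any change the test called 0.44 genes on average, and camera at the preset correlation called 0.36 lists on average, with at least 1 list in 14 draws. Genes were simulated independently of each other. In the real data the estimated correlation was 0.04 in the unfolded protein response list and 0.88 in the mast cell and eosinophil list. The draws therefore do not give the rate of false list calls in these data.

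The alternatives were pseudocounts of 0.1 and 0.5 FPKM, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to a common total, eBayes without trend, robust eBayes, array weights, a replicate block, leaving out each library, a minimum absolute log2 fold change of 1, and leaving out repeated names. A covariate for Y-linked transcripts and the removal of WT 2 together with R122C 3 were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.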

Results

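The data were FPKM values of corpus tissue from 3 WT and 3 R122C mice, 1 library per mouse. The corpus is the acid-secreting part of the stomach, whose glands hold pit, mucous neck, parietal and chief cells around a proliferating isthmus. Depth was estimated at 31700000 to 42900000 fragments in the 4 libraries where it could be recovered. The 10 most abundant genes took 46.1%, 45.3% and 46.2% of the summed FPKM in WT 1, WT 2 and WT 3, and 24.5%, 29.1% and 29.1% in R122C 1, R122C 2 and R122C 3. Pairwise correlations of log2 values across genes were between 0.96 and 0.98 within WT and between 0.92 and 0.98 within R122C, where R122C 3 stood farthest from the others. The first principal component held 57.0% of the variance and separated the groups, with R122C 3 at its end. The Y-linked genes Ddx3y and Eif2s3y were detected in WT 3 and R122C 2, and Xist in the other 4 libraries, so each group held 1 library with Y-linked transcripts.

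Runx3, the mutated gene (chromosome 4, 135120652 to 135177990, plus strand, up to 6 exons per annotated transcript), was scarcely detected in whole corpus tissue. Its level was 0.34, 0.12 and 0.20 FPKM in WT 1, WT 2 and WT 3, and 0.24, 0.34 and 0.95 FPKM in R122C 1, R122C 2 and R122C 3. The means were 0.22 ± 0.11 (SD, n = 3) in WT and 0.51 ± 0.38 (SD, n = 3) in R122C, a log2 difference of 0.28 ± 0.18 (SE), which did not pass an exact permutation test (p = 0.3, smallest possible 0.1). A point mutation need not alter transcript level, and a gene at this level does not check the labels. Runx1, another member of the family, was at 5.34 ± 1.06 FPKM in WT and 6.74 ± 0.78 in R122C (SD, n = 3) and did not pass either (limma adjusted p = 0.471).

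The comparison asks how expression in the corpus differs between R122C and WT mice, in particular for stem cell and differentiation genes. R122C tissue had more transcripts of mucous neck cell, metaplasia, tuft cell, interferon and MHC class I genes and of several secretoglobins, and fewer of the pit cell mucin Muc5ac. Of 11422 genes tested, 602 were higher and 95 lower in R122C, and 512 and 88 of these changed by at least 1 on the log2 scale. The values of the groups did not overlap for 25.5% of tested genes, where chance gives 10%, and 2300 had an unadjusted limma p under 0.05. The split of calls depended on scaling. With median-of-ratios scaling 419 genes were higher and 192 lower, with quantile normalization 405 and 248, and with rescaling to a common total 1318 and 83. The median change of tested genes moved from 0.10 to -0.0028, -0.06 and 0.30. The median of the shifts of the single genes was -0.11, -0.16 and 0.22, and single genes could shift by other amounts. None of the 697 changed genes had the opposite sign under any alternative in which it was tested. Fewer genes passed without WT 2 (246 higher, 18 lower), without WT 3 (330 and 35) and without R122C 2 (298 and 14), and more were lower without R122C 1 (566 and 195).

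**Figure D1:**
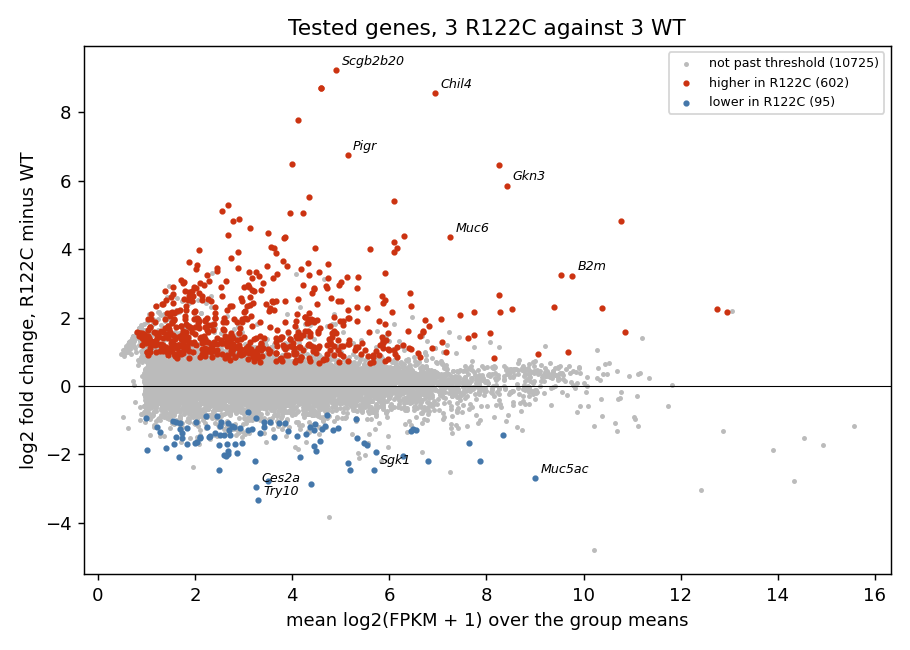
Each point is 1 of the 11422 tested genes, with the mean log2(FPKM + 1) of the groups on the x axis and the log2 fold change of R122C minus WT on the y axis. The 602 genes higher in R122C (red) outnumber the 95 lower (blue), and Scgb2b20 has the largest rise at 9.24.

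The 10 largest rises included 5 secretoglobins, Chil4, Pigr and Bpifb1. Scgb2b20, a secretoglobin (chromosome 7, 33364343 to 33366322, minus strand), was at 0.22 ± 0.10 FPKM in WT and 857 ± 577 in R122C (SD, n = 3), a log2 fold change of 9.24 ± 0.42 (SE, limma adjusted p = 2.99e-05). Scgb2b15 and Scgb2b17 had identical values and a fold change of 8.70, Scgb1b20 of 7.78 and Scgb2b7 of 6.50. These genes lie in 1 cluster on chromosome 7 and resemble each other, so reads may be shared and each value is uncertain. Chil4, a chitinase-like protein, rose by 8.55 ± 0.89, from 6.80 ± 5.38 to 4135 ± 5141 FPKM (SD, n = 3), with 10066 FPKM in R122C 3. Pigr, which carries IgA across epithelium (chromosome 1, 130826684 to 130852249, plus strand), rose by 6.75 ± 0.25 from 2.42 ± 0.50 to 377 ± 106 FPKM (adjusted p = 9.28e-06). Bpifb1, of the bactericidal/permeability-increasing fold family, rose by 6.45 ± 0.41.

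Mucous neck cell genes rose and a part of the pit cell genes fell. Of 6 neck genes, 5 rose, with a median log2 fold change of 3.25 (camera adjusted p = 2.28e-08, and adjusted p = 0.291 with an estimated correlation), and 6 rose when adjusted over the list alone. Without WT 2, 3 passed. The gel-forming mucin Muc6 (chromosome 7, 141633456 to 141655319, minus strand) went from 40.5 ± 25.7 to 720 ± 268 FPKM (SD, n = 3), a fold change of 4.35 ± 0.56. Gkn3, a gastrokine, rose by 5.86 ± 0.36 and Aqp5, a water channel, by 5.54 ± 0.29. Aqp5 lay at only 1.16 to 2.90 FPKM in WT, whose glands also hold neck cells, so its rise need not come from normal neck cells. Tff2, the spasmolytic polypeptide, rose by 2.16 ± 0.33 (adjusted p = 0.00741, and 0.0544 without WT 2). Of 9 pit genes, 2 fell and 7 did not pass, with a median of -1.24 (camera adjusted p = 4.64e-07, and adjusted p = 0.291 with an estimated correlation), and 6 fell when adjusted over the list alone. The count was 4 without WT 1 and 1 without WT 2, WT 3, R122C 2 or R122C 3. Muc5ac (chromosome 7, 141788972 to 141819231, plus strand) fell by 2.70 ± 0.33 on the log2 scale, from 1356 ± 437 to 207 ± 70.2 FPKM. Capn8, a stomach calpain, had a log2 fold change of -1.24 ± 0.29 (adjusted p = 0.0434) that did not pass without WT 2 (0.124), WT 3 (0.0823), R122C 2 (0.148) or R122C 3 (0.0676). Tff1, the transcript of highest mean in WT, was at 78990 ± 34420 FPKM in WT and 32750 ± 5398 in R122C and did not pass (adjusted p = 0.249), and in WT 1 it lay at 39246 FPKM, below Pgc at 97962.

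**Figure D2:**
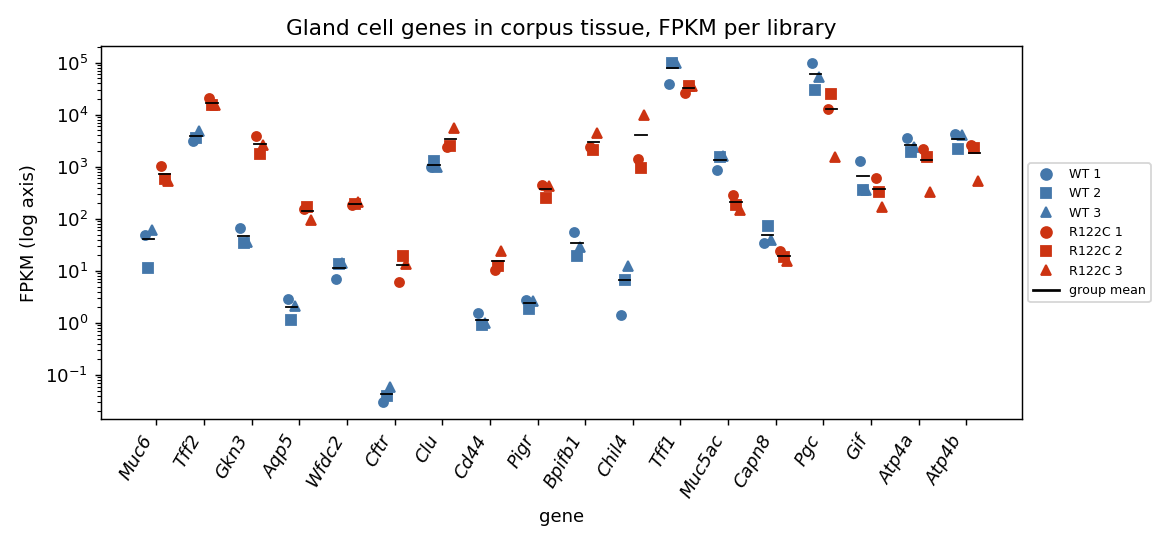
FPKM on a log axis for 18 gland cell genes, with a symbol per library (WT blue, R122C red) and a black line at each group mean. Muc6 is at 11.6 to 60.9 FPKM in WT and 537 to 1028 in R122C, whereas Pgc, Atp4a and Atp4b are lowest in R122C 3.

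Chief and parietal cell genes had lower medians, with no gene of either list past the threshold. Of 7 chief genes and 16 parietal genes tested, 0 passed, and the list medians were -0.74 and -1.01 (camera adjusted p = 0.0282 and 5.88e-06, and adjusted p = 0.507 for each with an estimated correlation). At an unadjusted limma p under 0.05, 2 chief genes were lower, and 5 parietal genes were lower and 1 higher. Adjusted over the list alone, 0 passed in either list. Without R122C 3 the medians were -0.27 and -0.38, and 1 chief and 2 parietal genes were called lower. Without R122C 1 they were -1.20 and -1.55, with 2 parietal genes called lower, and without WT 1 the chief median was -0.13. Pgc, encoding pepsinogen C, was at 60860 ± 34260 FPKM in WT and 13010 ± 11540 in R122C (SD, n = 3, adjusted p = 0.143), with 1537 FPKM in R122C 3. Atp4a, the catalytic subunit of the proton pump, was at 2670 ± 853 and 1366 ± 964 FPKM (adjusted p = 0.306), with 326 in R122C 3. The parietal median was -2.37 in R122C 3 against the WT mean, -0.72 in R122C 2 and -0.05 in R122C 1. The chief list did not pass without WT 1 (0.108) or R122C 1 (0.0533), nor with no filter (0.103), median-of-ratios scaling (0.104), quantile normalization (0.262) or array weights (0.393).

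Genes of spasmolytic polypeptide-expressing metaplasia (SPEM), a gland state with neck cell features, rose. Of 10, 8 rose, with a median of 2.35 (camera adjusted p = 2.49e-08, and adjusted p = 0.291 with an estimated correlation), and 9 rose when adjusted over the list alone. The count was 5 without WT 1, WT 2, WT 3 or R122C 2 in turn, and 5 with median-of-ratios scaling or quantile normalization. Wfdc2, a secreted protease inhibitor-like protein, rose by 4.01 ± 0.26 from 11.6 ± 3.95 to 194 ± 14.2 FPKM (SD, n = 3). Cftr, a chloride channel, rose by 3.63 ± 0.36, Sftpd, surfactant protein D, by 3.52 ± 0.48 and Cd44, a hyaluronan receptor, by 2.88 ± 0.30. The list's medians per library were 1.43, 2.19 and 3.35 in R122C 1, R122C 2 and R122C 3 against the WT mean. Because SPEM has neck cell features, the neck and SPEM lists do not tell more neck cells from metaplasia. Of 9 intestinal genes 4 rose and 1 fell (4 and 2 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.637). Without WT 2 or WT 3, 2 intestinal genes were called higher, and without R122C 2 only 1, while 0 were called lower without WT 2, R122C 1 or R122C 2. Spink4, a goblet cell protein, rose by 2.67 ± 0.40, while the intestinal regulators Cdx1 and Cdx2 stayed at or under 0.11 FPKM in every library.

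Tuft cell genes rose, 6 of 8 and also 6 when adjusted over the list alone, with a median of 1.46 (camera adjusted p = 1.69e-06, and adjusted p = 0.291 with an estimated correlation). Without WT 2, 3 tuft genes passed. Alox5ap, needed for leukotriene synthesis, rose by 2.27 ± 0.32 and Rgs13 by 1.79 ± 0.25. Dclk1, a widely used tuft marker, rose by 1.28 ± 0.23 (adjusted p = 0.0165, and 0.0877 without WT 2). Of 8 enteroendocrine genes 0 passed limma, 1 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.901), and Ghrl, encoding ghrelin, was at 898 ± 351 FPKM in WT and 1789 ± 67.8 in R122C (SD, n = 3, adjusted p = 0.0813, and 0.0245 without WT 1).

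Among 8 reported stem cell genes of the corpus, 1 rose, 2 when adjusted over the list alone, and the list did not pass (median 0.36, camera adjusted p = 0.158), with a median of 0.14 without WT 2 and 0.57 without WT 1. That gene was Sox9, a progenitor transcription factor, with a change of 1.22 ± 0.28 and an adjusted p of 0.0421 that lay between 0.0586 and 0.119 without each of the 6 libraries in turn. Stmn1 and Iqgap3, reported isthmus markers, had log2 fold changes of 0.43 ± 0.28 and 0.47 ± 0.28 (adjusted p = 0.455 and 0.392). All 22 S phase genes tested and all 25 genes of G2 and mitosis had a log2 fold change above 0, with medians of 0.46 and 0.61, of which 2 and 0 passed limma, 3 and 3 when adjusted over the list alone and 10 and 10 at an unadjusted p under 0.05 (camera adjusted p = 0.000338 and 6.8e-05, and adjusted p = 0.507 for each with an estimated correlation). Tyms and Ung, of DNA synthesis and repair, rose by 0.79 ± 0.17 and 1.01 ± 0.23, and each did not pass in 5 of the 6 fits that left out 1 library (up to 0.142 without R122C 2 and 0.177 without WT 2). Without WT 2 the medians were 0.29 and 0.34, and 0 S phase genes passed without WT 1, WT 2, WT 3 or R122C 2, and 1 without R122C 1 or R122C 3, while 1 gene of G2 and mitosis passed without WT 3 or R122C 1. When WT 2 and R122C 3 were left out together, a choice made after seeing the data, the camera adjusted p was 0.0548 for S phase and 0.0648 for G2 and mitosis.

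Interferon-stimulated genes and MHC class I genes rose in all 3 R122C libraries. Of 21 interferon genes 17 rose, and 20 when adjusted over the list alone, with a median of 2.81 (camera adjusted p = 1.41e-17, and adjusted p = 0.291 with an estimated correlation). Ifi44 rose by 3.92 ± 0.32, Ifit3 by 3.50 ± 0.37, Mx1, an antiviral GTPase, by 3.34 ± 0.33 and Ddx58, the RNA sensor RIG-I, by 2.48 ± 0.25. The antigen presentation list covers both MHC class I and class II. Of its 14 tested genes 9 rose, with a median of 2.15 (camera adjusted p = 9.08e-13, and adjusted p = 0.291 with an estimated correlation), and 14 rose when adjusted over the list alone. B2m, the light chain of MHC class I, went from 296 ± 109 to 2816 ± 1033 FPKM (SD, n = 3) and H2-K1, a heavy chain, from 243 ± 44.0 to 2351 ± 725. Psmb8, of the immunoproteasome, rose by 3.42 ± 0.35 and Nlrc5, the class I transactivator, by 2.05 ± 0.23. Of 7 inflammatory and defence genes 2 rose and 1 fell (3 and 1 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0758). It did pass without WT 2 (0.0352), WT 3 (0.0222), R122C 1 (0.0031) or R122C 2 (0.0369). It also passed with a pseudocount of 0.1 (0.0449), no filter (0.00155), the replicate block (0.0409) or the Y-linked covariate (0.0241). Only 1 rose without WT 1, WT 2, WT 3 or R122C 2, and 0 fell without WT 2, WT 3 or R122C 2. The lectin Reg3g rose by 4.81 ± 0.49, and Reg3b was listed at 0 in all 3 WT libraries and at 1.02, 10.67 and 12.27 FPKM in R122C 1, R122C 2 and R122C 3.

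**Figure D3:**
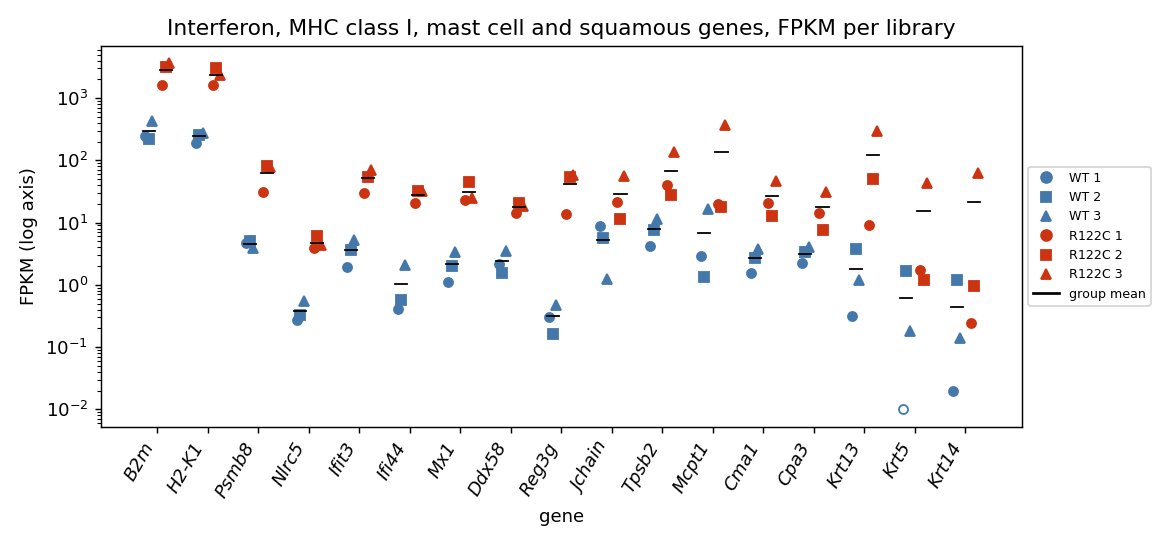
FPKM on a log axis for 17 genes of the interferon, MHC class I, mast cell, plasma cell and squamous lists, with a symbol per library and a black line at each group mean, and an open symbol at the bottom for a value listed at 0. B2m lies at 222 to 422 FPKM in WT and 1658 to 3643 in R122C, whereas Krt5 and Krt14 are high in R122C 3 alone.

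Mast cell and eosinophil genes rose, 6 of 8, and 8 when adjusted over the list alone, with a median of 2.35 (camera adjusted p = 5.88e-06, and adjusted p = 0.482 with an estimated correlation). The count was 1 without WT 2, 2 without WT 1, 3 without R122C 1, and 2 with median-of-ratios scaling or quantile normalization. Cma1, a mast cell chymase, rose by 2.78 ± 0.44, and the list's median was 3.36 in R122C 3 against 1.91 in R122C 1 and 1.44 in R122C 2. Of 7 macrophage genes 1 rose, the lipopolysaccharide co-receptor Cd14 by 1.58 ± 0.31 (adjusted p = 0.0875 without WT 2 and 0.0816 without WT 3), and the list (camera adjusted p = 0.0364, and adjusted p = 0.507 with an estimated correlation) did not pass without WT 3 (0.109), R122C 2 (0.0601) or R122C 3 (0.0899). Nor did the macrophage list pass with no filter (0.0854), at a mean of at least 5 FPKM (0.17) or after rescaling to a common total (0.0825). Of 3 plasma cell genes 0 passed limma and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.224). Of the T and NK cell list no gene reached the filter, and Cd3e was at or under 0.86 FPKM in every library. The neutrophil list had 2 tested genes, of which Retnlg rose by 1.94 ± 0.30.

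The listed squamous genes of the neighbouring forestomach were high mainly in R122C 3. Of 14 tested, 1 rose, Krt13, a keratin, at 9.17, 49.64 and 300.87 FPKM in R122C 1, R122C 2 and R122C 3 against 0.32 to 3.77 in WT (adjusted p = 0.043, and 0.112 without WT 1, 0.0915 without WT 2, 0.11 without WT 3 and 0.122 without R122C 2). Without R122C 3 Krt13 still passed, with a log2 fold change of 3.24 (limma adjusted p = 0.0187). Krt5 was at 42.9 FPKM and Krt14 at 63.3 in R122C 3, and both were at or under 1.70 in the other 5 libraries. The list passed (camera adjusted p = 0.00765, and adjusted p = 0.57 with an estimated correlation) but not without R122C 3 (0.309) or WT 1 (0.0953), nor after rescaling to a common total (0.12). Its median of 1.90 was 1.06 without R122C 3, where only 6 of its genes reached the filter. Of 3 antral genes 1 rose, the hormone gene Gast, at 2.10, 3.55 and 2.99 FPKM in R122C and at or under 0.86 in WT (adjusted p = 0.0183, and 0.0503 without WT 1, 0.0902 without WT 2 and 0.0827 without R122C 2), and the list did not pass (0.144) but did without WT 3 (0.04, median 1.41). Adjusted over the list alone, 2 antral genes rose, and 1 of the 3 had a log2 fold change below 0. Pdx1, of the antral list, was at 0.14, 2.09 and 1.65 FPKM in WT 1, WT 2 and WT 3. It was at 2.38, 4.91 and 5.27 FPKM in R122C 1, R122C 2 and R122C 3 (limma adjusted p = 0.125). R122C 3 was also the library with the lowest parietal and chief medians.

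**Figure D4:**
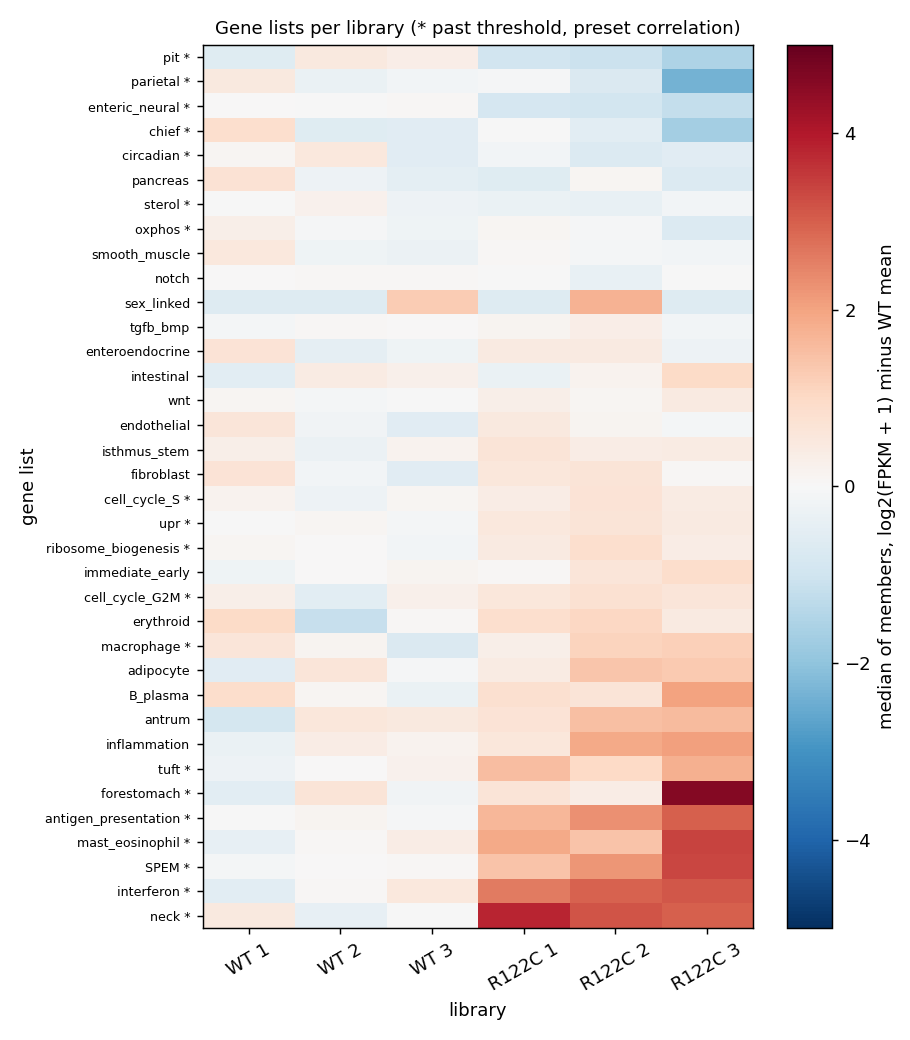
Median over list members of log2(FPKM + 1) minus the WT mean, for the 36 tested lists (rows, ordered by median log2 fold change) and the 6 libraries (columns). The forestomach list reaches 4.60 in R122C 3 and 0.64 and 0.37 in R122C 1 and R122C 2, whereas the neck list is at 3.79 in R122C 1 and above 0 in all 3.

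Unfolded protein response genes had a median of 0.54, with 1 of 16 past the threshold and 6 when adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.291 with an estimated correlation). The count was 0 without WT 1, WT 2, WT 3 or R122C 2, 3 without R122C 1 and 2 without R122C 3. Ribosome biogenesis genes had a median of 0.58 with 0 of 15 past the limma threshold, 5 when adjusted over the list alone and 9 at an unadjusted p under 0.05 (0.000338, and adjusted p = 0.507 with an estimated correlation). Enteric neuron and glia genes had a median of -0.95, and 2 of 4 fell (0.000673, and adjusted p = 0.291 with an estimated correlation), Snap25, of synaptic vesicle release, and Uchl1, a neuronal hydrolase. Each of these lost its call in 4 of the 6 fits without 1 library, up to 0.111 without WT 2 and 0.121 without WT 3. Oxidative phosphorylation genes (median -0.19, 0 of 23, 0.0021, not passing without R122C 3 at 0.0958, where the median turned to 0.04, as it did after rescaling to a common total, and was -0.04 without WT 1, -0.28 without R122C 2, -0.31 without WT 3 and -0.36 without R122C 1), sterol genes (-0.27, 0 of 10, 0.0103, not passing without WT 2 at 0.105 or R122C 1 at 0.14) and clock genes (-0.38, 0 of 11, 0.0086, and without WT 3 a median of -0.64 with 2 genes called lower, and 1 without R122C 1 or R122C 3) passed camera at the preset correlation. At an unadjusted limma p under 0.05 they had 1 lower, 1 higher and 1 lower, and 2 lower genes, and 0 when adjusted over the list alone. They had adjusted p = 0.585, 0.507 and 0.389 with an estimated correlation. The clock list did not pass at a mean of at least 5 FPKM (camera adjusted p = 0.0533) or with quantile normalization (0.054). Smooth muscle (camera adjusted p = 0.218), fibroblast (0.251), endothelial (0.924), exocrine pancreas (0.0687), adipocyte (0.0838) and red blood cell lists (0.331) did not pass in the main fit, nor did the Wnt (0.351), Notch (0.218), TGF-beta and BMP (0.718), immediate early (0.151) and sex-linked lists (0.696). Leaving out 1 library gave a call for the pancreas list (lower, 0.0248 without WT 2 and 0.0258 without R122C 2) and, higher, for the adipocyte (0.0139 without WT 2 and 0.0094 without R122C 1), fibroblast (0.00405 without WT 1) and immediate early lists (0.0367 without WT 3 and 0.0036 without R122C 1), and rescaling gave one for pancreas (0.0171). For the TGF-beta and BMP and the sex-linked lists the median and the camera direction differed in sign. In all, 12 lists were higher and 7 lower at the preset correlation. With an estimated correlation 0 passed after adjustment and 6 had an unadjusted p under 0.05, and fry called 6 higher and 0 lower. The lists called by fry were neck (fry adjusted p = 0.00529), tuft, SPEM, interferon and antigen presentation (0.0126 each) and unfolded protein response (0.0181). The pit list and the mast cell and eosinophil list did not pass fry (0.0765 each). The RUNX list had 2 tested genes, too few for a test.

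The largest falls were smaller than the largest rises. Ugt1a7c, a glucuronosyltransferase, fell by 2.76 ± 0.35, Sgk1, a kinase controlled by hormones and salt, by 2.45 ± 0.37 and Slc5a5, the iodide transporter, by 2.45 ± 0.32. Slco2a1, a prostaglandin transporter, fell by 2.26 ± 0.38 (adjusted p = 0.0125, and 0.0557 without WT 2) and the carboxylesterase Ces2a by 2.95 ± 0.57 (0.0203, and 0.0692 without R122C 2). Smim24 and B4galnt2 each did not pass in 3 of the 6 fits without 1 library, up to 0.094 and 0.0763 without WT 2. The digestive enzymes Try10, a trypsin with close relatives that can share its reads, and Amy2a5 fell by 3.34 ± 0.76 and 2.88 ± 0.67, and each did not pass in 4 of those fits, up to 0.0749 without WT 2 and 0.112 without WT 1. Both were highest in WT 1, at 91.6 and 88.8 FPKM. Try4, of the exocrine pancreas list, was also highest in WT 1, at 404 FPKM, with a log2 fold change of -3.83 (limma adjusted p = 0.058). Cela1, of the same list, had a log2 fold change of 0.82 (0.244).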

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

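Removing WT 2 with R122C 3 and the Y-linked covariate were chosen after seeing the data. Of 63 named genes past the threshold, 34 stayed past it under every alternative in which they were tested, and none of the 63 reversed. Of 1248 such alternative values 1072 kept direction and call and 176 kept direction only. Named genes not past the threshold gained a call in 63 of 877 alternatives, 30 with array weights, and lists not past it in 27 of 364, of which 8 were the inflammation list. Of 19 lists past the threshold, 6 lost the call only with an estimated correlation. For Runx3 the alternatives were run with limma without the filter, not with the permutation test. Runx3 had a limma adjusted p of 0.479 with the main settings and passed under no alternative. The alternatives that change the filter could not change its value. The 697 changed genes (602 higher, 95 lower) became 449 (392, 57) at a mean of at least 5 FPKM, where fewer genes were tested, 1401 (1318, 83) after rescaling to a common total and 438 (393, 45) without WT 2 and R122C 3, where samples were fewer. Lower genes became 192 with median-of-ratios scaling, 248 with quantile normalization and 62 with the Y-linked covariate, and the cause was not tested. Array weights gave 5509 (3812, 1697), but their estimation stopped before converging, with a weight of 38.8 on R122C 2 and 0.239 to 2.24 on the others. Leaving out 1 library gave 264 to 761 genes, 246 to 581 higher and 14 to 195 lower. The 19 lists became 0 with an estimated correlation and 6 with fry. Depth limits low genes such as Runx3, and the depth of R122C 1 and R122C 2 is undetermined.

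The replicate block gave 1378 genes (1119 higher, 259 lower). With the block the inflammation (camera adjusted p = 0.0409), adipocyte (0.0363) and immediate early (0.0451) lists passed, which did not in the main fit. Of the parietal list 4 genes were called lower with the block. Deviations of same-numbered libraries from their group means correlated across genes at 0.47, 0.02 and 0.37, and 4 of the 6 libraries correlated best with their own number in the other group. WT 2 correlated best with R122C 3 (0.11) and R122C 2 with WT 1 (0.10). The labels name no pairs, so the fit without the block was kept. Of the 3 same-numbered values 1 was under 0.1, so these values do not settle whether the numbers are pairs.

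Directions reversed as follows, with no reversed value past the threshold, and the cause was not tested. For lists the direction is that of the test, which can turn while the median, given here, keeps its sign. With fry, the TGF-beta and BMP list (median 0.13) and the sex-linked list (0.11) turned, as did the former without a filter (0.155). With quantile normalization Tff1 became 0.25 and the sex-linked list -0.017. With rescaling Cdh5 became 0.091, and the intestinal (0.40) and endothelial (0.46) lists turned. With array weights Hba-a2 became -0.72 and S100a9 -0.091, and the intestinal (0.12), forestomach (0.0086) and sex-linked (2.02) lists turned. Without WT 2 and R122C 3 Acta2 became -0.0345 and Hba-a2 -0.29, and the enteroendocrine (0.16) and endothelial (0.31) lists turned. Over the fits without 1 library the range was -0.13 to 0.69 for Col1a2, -0.032 to 0.87 for Pecam1, -0.35 to 0.33 for Cdh5 and -0.19 to 0.54 for Ddx3y. List medians ranged from -0.0054 to 0.53 (enteroendocrine), -0.15 to 0.995 (intestinal), 0.18 to 0.80 (fibroblast), 0.034 to 0.51 (endothelial), -0.038 to 0.19 (TGF-beta and BMP) and -0.26 to 0.42 (sex-linked), and each of these lists turned in at least 1 fit.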

Other observations

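The tests of mast cells, of cell dilution and of antral tissue were chosen after the result was seen, as were the genes and families in the next paragraph. The other tests were written down before their result was seen.

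Of 18 gene families looked at after the values were seen, several had many members that rose. All 9 tested H2-Q genes and all 3 tested H2-T genes, nonclassical MHC class I, rose, as did 7 of 8 Oas genes, 4 of 5 Ifit genes, 4 of 6 immunity-related GTPases, 3 of 5 Gbp genes, 6 of 8 secretoglobins and 5 of 6 Wfdc genes. Some of these, among them Oas1a, Ifit3, Gbp3 and Wfdc2, belong to the fixed interferon and SPEM lists and are counted there too. Since the families were picked after the values were seen no enrichment is claimed, and related members can share reads. Of 11 Sprr2 genes, of the small proline-rich proteins, 2 rose, Sprr2a1 (limma adjusted p = 0.0267) and Sprr2a3 (0.00543). Sprr2a3 was at 168 to 793 FPKM in WT and at 4348, 8427 and 21836 FPKM in R122C 1, R122C 2 and R122C 3. Klk1, a kallikrein, rose by 5.41 ± 0.38 from 10.3 ± 4.86 to 465 ± 157 FPKM (SD, n = 3), and Cldn2, a tight junction protein, by 3.97 ± 0.35. The neuropeptide gene Tac1 fell by 2.08 ± 0.23 and the glutathione transferase gene Gsta3 by 1.53 ± 0.22, each past the limma threshold without any 1 library. Vip, Grp and Aldh3a1 fell by 1.72 ± 0.37, 1.69 ± 0.38 and 1.67 ± 0.38 and did not pass in 3, 4 and 3 of the 6 fits without 1 library. The highest adjusted p was 0.133 for Vip and 0.141 for Aldh3a1 without WT 2, and 0.121 for Grp without R122C 2.

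The real split of the 6 libraries called 697 genes and the highest of the other splits 1. With 10 splits a share under 0.05 cannot be reached (1 of 10 gave as many).

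Squamous genes lay higher in the R122C group, with 1 of 14 past the threshold and the list's call lost with an estimated correlation (adjusted p = 0.57). A candidate explanation is forestomach tissue in R122C 3, and 12 of 13 genes of a second squamous list were highest in that library, among them Krt1 at 144 FPKM and Cnfn at 139.5 FPKM. An effect shared by all 3 R122C libraries stays open. The first list had a camera adjusted p of 0.309 without R122C 3, and a lost call was set in advance to count against this, which was wrong because the median without R122C 3 was still 1.06, though over only the 6 genes that reached the filter then, and Krt13 in R122C 1 and R122C 2 (9.17 and 49.64 FPKM) lay above all WT values. The list's medians in R122C 1 and R122C 2, 0.64 and 0.37 against the WT mean, did not lie clearly above that of WT 2 at 0.63. Squamous change within the corpus of the R122C 3 mouse was not tested and stays open.

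Interferon and MHC class I genes were higher in R122C. Scaling against abundant transcripts is argued against, because the interferon median was 2.69 with median-of-ratios scaling. More leukocytes of all kinds as the sole source is argued against by a leukocyte list, whose median was 1.22 (interquartile range 1.05 to 1.32) against 2.65 for 8 class I genes. The bound set in advance, 0.5 times the class I median, was 1.33, and over 12 combinations of pseudocount and scaling, run after the result was seen, the leukocyte median lay under the bound of that combination by only 0.016 to 0.22, with the upper quartile under it in 3. More mast cells and eosinophils cannot be told apart from a change in other cells, because their list had a median of 2.35, close to that of the class I genes, while from R122C 1 to R122C 2 all 8 mast cell and eosinophil genes were lower and all 8 class I genes higher, which compares single libraries only. Since 5 of 10 leukocyte genes rose, immune cells may hold a part, and a genotype effect on the epithelium stays open as a hypothesis, as does an infection or housing difference, which was not tested.

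Neck and SPEM genes were higher in R122C, and 2 of 9 pit genes passed as lower. With an estimated correlation each of these lists had a camera adjusted p of 0.291. A lower share of pit, chief and parietal cells would raise other cell types alike, but 40 stromal and enteroendocrine genes had a median of 0.21 (interquartile range -0.06 to 0.41) against 3.25 for the neck list. Antral tissue in the R122C libraries cannot be told apart from a change of the corpus glands, because 1 of 3 antral genes rose (Gast), and 2 when adjusted over the list alone. The antral list passed camera without WT 3 (0.04) only, and antral glands also express Muc6, Tff2 and Aqp5. A genotype effect stays open, as a hypothesis.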
